A study of Mus musculus with 10 samples.

How the data were processed

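Regulatory T cells were sorted by a red fluorescent reporter from tumor and LN of control mice (3 libraries per tissue) and of mice without MHC class II on lymphatic endothelial cells (2 libraries per tissue). Per the labels, RNA was reverse transcribed and amplified with the SMARTer Ultra Low kit, made into libraries with Nextera XT and sequenced as single reads of 50 bases. The processing notes name CASAVA 1.8.2, STAR 2.4, featureCounts 1.4.6 and the build GRCm38. The sources used here do not state the annotation release or the strand setting of the counting.

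The authors deposited raw counts per Ensembl gene, with 1 column per library and no normalization. The values are whole numbers, and each library sums to its own total of 28539329 to 35736175 counts. All 21556 gene identifiers were matched to GENCODE M21, which gave symbols and positions: 21066 rows are protein coding genes, 455 are immunoglobulin or T cell receptor segments and 35 are polymorphic pseudogenes. There are 0 mitochondrial genes among them, so that list was not tested. In all, 4630 genes have a count of 0 in every library. The floor for a count of 0 was set at 3 counts, which is 0.0839 to 0.105 CPM for a single library. Where all libraries of a group were at 0, a fold is given as a lower bound against 3 counts over the group.

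Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 4 groups (minimum count 10), which left 13920 genes, and libraries were normalized with TMM. A quasi-likelihood negative binomial model with robust spread was fitted to all 10 libraries as 4 group means, because groups of 2 give little information on their own spread. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are TMM-normalised group means with SD. The comparisons were the deletion effect in tumor and in LN, the tissue effect in control and in MHCII-deleted mice, and the difference of the deletion effects as an interaction. The overlap of the tissue effects was counted against the product of both counts over all tested genes. Principal components used log2 CPM with a prior count of 2.

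Samples, comparisons, gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. The rule takes, per comparison, the 10 called genes with the largest change in each direction among those with at least 10 CPM and no overlap between the replicates (no overlap rule for the interaction), up to 4 called members of each list by p, and 10 genes reported throughout. It leaves out predicted genes and receptor segments. The rule named 109 genes for the deletion effect in tumor, 60 in LN, 119 for each tissue effect and 91 for the interaction. Of these, 40, 17, 52, 32 and 25 were carried through every alternative, in the order tumor deletion, LN deletion, tissue effect in control mice, tissue effect in MHCII-deleted mice and interaction. This choice among the genes that the rule named was made after their values had been seen. The values of 3 of them are not reported here, and the others are printed. Slc16a5 was left out of it for the interaction because it had a count of 0 in every tumor library of control mice, so that its fitted difference is no bound.

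The 26 lists cover Treg identity, Treg suppressive and effector molecules, the tumor Treg signature, the naive and central T cell program, TCR-induced and immediate early genes, cell cycle, type I interferon response, interferon gamma and Th1-like program, Th2 and tissue repair, Th17-like program, chemokine receptors and adhesion, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, heat shock and dissociation stress, unfolded protein response, apoptosis regulators, MHC class II presentation, ribosomal protein genes, mitochondrially encoded genes, and markers of melanoma, myeloid, B and plasma, CD8 T and NK, stromal and endothelial, and erythroid and platelet cells. Lists share genes: Ctla4, for example, is in both the identity and the suppressive list. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists tested. Members past the threshold were counted over all genes and adjusted over the list alone. A list of 24 pan-T cell genes and a list of lymphatic endothelial markers were added after the data had been seen and were not tested with camera.

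Alternatives fixed beforehand were size factors by the RLE method, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a non-robust spread, only the groups compared, no receptor segments, a replicate block and the omission of each library. Chosen after seeing the data were scaling to pan-T cell genes, leaving out genes with a GC-rich window (more than 75% GC in some 100-base window of a transcript), both together, a GC index per library as a covariate, and libraries of 1 level of that index. The index is the mean centred log2 level of genes with a window above 80% GC minus that of genes at or under 70%, over genes with a mean log2 CPM above 4 in LN.

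The test was checked on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 41% and 80% of them in the tumor deletion comparison, 41% and 81% in the LN one, 48% and 84% in the tissue comparison of control mice and 36% and 70% in that of MHCII-deleted mice. False calls made up 1.5% to 5.3% of all calls. The oxidative phosphorylation list was raised 2-fold as well and counts among the true calls. All simulated libraries shared 1 baseline, without uneven GC content or a shift in composition. These shares therefore do not carry over to comparisons of the real libraries where such differences exist.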

Results

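RNA was measured in regulatory T cells (Tregs) that had been sorted by a red fluorescent reporter from mice bearing a lymphangiogenic melanoma. The cells came from the tumor or from a lymph node (LN), and the mice were 10 weeks old. In MHCII-deleted mice, a Cre recombinase under Prox1 control removes MHC class II from lymphatic endothelial cells, and control mice carry the floxed allele without Cre. There were 3 LN and 3 tumor libraries from control mice and 2 LN and 2 tumor libraries from MHCII-deleted mice. The total count per library lay between 28539329 and 35736175, and 12825 to 14703 genes were detected in each. A count of 0 allows a level of up to 0.0839 to 0.105 CPM (counts scaled to a common library size), depending on the library. Such floors and intervals cover counting error only, because amplified reads carry no molecular identifiers.

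Tissue was the main axis of variation. The first principal component held 70.1% of the variance of the tested genes and placed all 5 LN libraries between -124.8 and -111. It placed the tumor libraries of control mice between 75 and 97.5 and those of MHCII-deleted mice at 158.4 and 166.4, so it also separated the genotypes in tumor. The second component held 8.4% and placed the tumor libraries of control mice between -63.7 and -42.1 and those of MHCII-deleted mice at 52.3 and 67.5.

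Foxp3, the lineage factor of Tregs (ENSMUSG00000039521, chromosome X, 7573644 to 7595245 in GRCm38), was expressed in every library. Its mean level was 687 ± 53.4 CPM (SD, n = 3) in LN and 738 ± 85.9 (SD, n = 3) in tumor of control mice, and 617 ± 52.4 (SD, n = 2) in LN and 346 ± 5.07 (SD, n = 2) in tumor of MHCII-deleted mice. Cd4 stood at 1160 ± 35.3, 1340 ± 98.2, 1120 ± 29.3 and 645 ± 17.5 CPM in the same order. Ctla4, a co-inhibitory receptor, stood at 495 ± 6.02, 3070 ± 186, 319 ± 35.5 and 1360 ± 181 CPM. Cd8a, a marker of cytotoxic T cells, did not exceed a group mean of 7.46 CPM. The deletion itself cannot be checked in these libraries, since it takes place in lymphatic endothelial cells and not in the sorted cells. H2-Ab1, which encodes an MHC class II chain, had a mean of 9.06 ± 4.09 CPM in LN of control mice and 16.0 ± 0.498 in LN of MHCII-deleted mice, a difference that did not pass the test (edgeR quasi-likelihood, adjusted p = 0.79). In tumor it stood at 59.5 ± 25.9 CPM in control mice and 27.2 ± 16.8 in MHCII-deleted mice (edgeR, adjusted p = 0.121). H2-Aa and H2-Eb1 did not pass in tumor (adjusted p = 0.571 and 0.419) or in LN (adjusted p = 0.732 and 1.0) by the same test. Prox1, the lymphatic regulator that drives the Cre, had group means of 0.951 to 4.51 CPM.

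Transcripts of other cell types were present in the tumor libraries, and their amounts differed between the genotypes. Melanoma markers summed to 5260 ± 1930 CPM (SD, n = 3) in tumor of control mice and 16900 ± 2500 (SD, n = 2) in tumor of MHCII-deleted mice, against 14.3 ± 4.97 and 23.6 ± 5.83 in LN. The 24 genes shared by T cells in general, a list made after the data had been seen and called pan-T cell genes here, summed to 24400 ± 731 CPM in tumor of control mice and 11300 ± 1170 in tumor of MHCII-deleted mice. In LN these genes summed to 27400 ± 447 and 26300 ± 21.2 CPM. Collagen genes summed to 2340 ± 1850 CPM in tumor of control mice, with 411 in library 1 and 4093 in library 2, and to 450 ± 265 in tumor of MHCII-deleted mice. Myeloid markers summed to 386 ± 74.7 and 618 ± 31.7 CPM in the tumor of the respective genotypes. Lymphatic endothelial markers, also listed after the data had been seen, summed to 40.3 ± 10.4 CPM in tumor of control mice, and to 109.2 and 415.5 in the tumor libraries of MHCII-deleted mice.

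**Figure D1:**
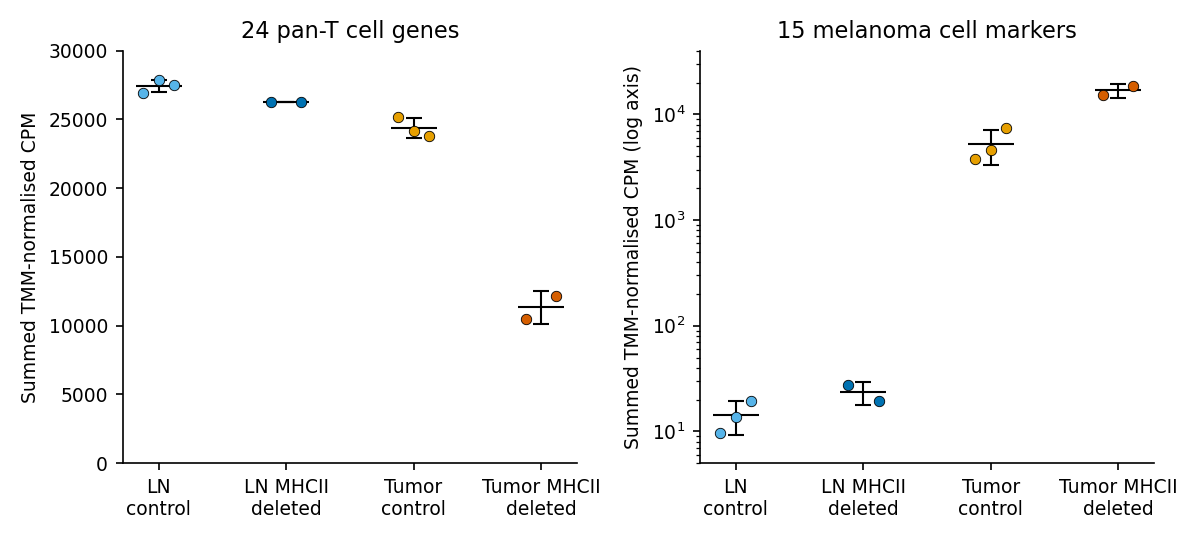
Summed TMM-normalised CPM of pan-T cell genes (left, linear axis) and of melanoma markers (right, log axis) in each library, with points for libraries and bars for the group mean and SD. Pan-T cell genes sum to 11300 CPM in tumor of MHCII-deleted mice against 24400 in tumor of control mice, and melanoma markers to 16900 against 5260.

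The deletion effect in tumor asks whether tumor Tregs differ when lymphatic endothelial cells lack MHC class II, the comparison behind the suppressive functions that the series title names. Relative to all counts of a library, Treg genes were lower and melanoma genes higher in tumor of MHCII-deleted mice. Foxp3 fell with a log2 fold change of -1.09 ± 0.12 (SE; edgeR quasi-likelihood, adjusted p = 0.000302), and Cd4 with -1.06 ± 0.09 (adjusted p = 0.000144), but both turn to 0.04 and 0.08 when libraries are scaled to pan-T cell genes. Tyrp1, a pigment enzyme of melanocytes (ENSMUSG00000005994, chromosome 4, 80834123 to 80851719), rose from 845 ± 179 CPM (SD, n = 3) to 3100 ± 266 (SD, n = 2), a log2 fold change of 1.87 ± 0.28 (adjusted p = 0.00155). The other melanosome genes Mlana and Slc24a5 rose with 1.47 ± 0.28 and 1.86 ± 0.34. Of 13920 genes tested, 2092 rose and 1907 fell.

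All 24 pan-T cell genes fell, with a median log2 fold change of -1.13. Of the 20 genes of Treg identity, 17 fell and 1 rose, with the same counts when adjusted over the list alone (median -1.11, or 0.00 scaled to pan-T cell genes). Among them Il2ra, the high-affinity interleukin 2 receptor chain, stood at -1.19 ± 0.16, and the costimulatory receptors Tnfrsf18 and Tnfrsf4 at -1.37 ± 0.12 and -1.33 ± 0.15. Rgs1, a regulator of chemokine receptor signaling, stood at -1.44 ± 0.16. Of 27 suppressive and effector genes, 22 fell and 1 rose, and 24 fell when adjusted over the list alone (median -1.11, turning to 0.03 with pan-T scaling). Ctla4 fell with -1.18 ± 0.11 (adjusted p = 0.000195), the transcription factor Batf with -1.34 ± 0.12, and Klrg1, a receptor of terminally differentiated effector cells, with -2.29 ± 0.32 (adjusted p = 0.00107). Il10, an immunosuppressive cytokine (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), fell from 78.2 ± 2.66 CPM (SD, n = 3) to 26.0 ± 3.64 (SD, n = 2), and Maf, a factor that drives its transcription, had -1.53 ± 0.15. Of the 28 genes of the tumor Treg signature, 26 fell, also when adjusted over the list alone (median -1.19, or -0.06 with pan-T scaling), among them the chemokine receptor Ccr8 with -1.32 ± 0.16. Camera called these 3 lists lower, with adjusted p = 6.05e-17, 4.67e-19 and 1.13e-21, and adjusted p = 0.0189 for each with an estimated correlation. In the same libraries, melanoma markers summed to 16900 CPM against 5260.

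In the list of TCR-induced and immediate early genes, 20 of 28 fell, 22 adjusted over the list alone, with a median of -1.12 that turns to 0.01 under pan-T scaling. The list's camera call (adjusted p = 2.5e-13) was lost, with adjusted p = 0.132 with an estimated correlation. Cd5, an attenuator of receptor signaling, stood at -1.19 ± 0.10, the NF-kB inhibitor Nfkbia at -1.28 ± 0.11 and the transcription factor Irf4 at -1.36 ± 0.15. Chemokine receptors and adhesion molecules had 16 of 24 genes lower, 18 adjusted over the list alone (median -1.15, or -0.03 with pan-T scaling), including the gut-homing integrin chain Itgb7 with -1.20 ± 0.10. That call (adjusted p = 1.01e-10) held with adjusted p = 0.0189 with an estimated correlation. The Th2 and tissue repair list had 9 of 13 genes lower and 1 higher, the same adjusted over the list alone (median -1.29, or -0.15 with pan-T scaling). Areg, an epidermal growth factor receptor ligand, and Gata3, the Th2 lineage factor, stood at -1.44 ± 0.17 and -1.29 ± 0.17. Its camera result was adjusted p = 1.43e-07, and adjusted p = 0.0901 with an estimated correlation. Of 9 Th17-like genes 4 fell, also adjusted over the list alone, with a median of -1.53, or -1.24 with the gene undetected in a whole group at its bound. With pan-T scaling the median was -0.39, with 1 gene higher and 1 lower. Camera gave that list adjusted p = 0.000265, and adjusted p = 0.0497 with an estimated correlation.

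The interferon gamma and Th1-like list had 18 of 23 genes lower and 1 higher, 20 and 1 adjusted over the list alone, with a median of -0.88 that turns to 0.23 with pan-T scaling (camera adjusted p = 2.35e-07, and adjusted p = 0.236 with an estimated correlation). Its cytokine gene Ifng had -1.46 ± 0.31, and Cxcl10, a chemokine induced by interferon, had -1.81 ± 0.54 (edgeR adjusted p = 0.034). Of 26 type I interferon genes 6 fell, also adjusted over the list alone, with a median of -0.89 that turns to 0.24 (camera adjusted p = 3.03e-05, and adjusted p = 0.447 with an estimated correlation). Ly6e, a member of that list, stood at -1.24 ± 0.08. Apoptosis regulators had 9 of 20 genes lower and 1 higher, 11 and 1 adjusted over the list alone, with a median of -0.57 that turns to 0.56 (camera adjusted p = 5.22e-05, and adjusted p = 0.0189 with an estimated correlation). Bcl2, which protects from apoptosis, was the member that rose, with 0.98 ± 0.18. MHC class II presentation had 5 of 11 genes lower, 6 adjusted over the list alone, with a median of -0.84 that turns to 0.27 (camera adjusted p = 0.00138, and adjusted p = 0.282 with an estimated correlation). Cd74, the invariant chain, had -1.17 ± 0.23. Of 47 ribosomal protein genes 4 fell, 2 adjusted over the list alone, with a median of -0.20 that turns to 0.95 (camera adjusted p = 0.0179, and adjusted p = 0.741 with an estimated correlation).

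Of 30 cell cycle genes 17 rose, 18 adjusted over the list alone (median 0.56), with Mcm2, a replication helicase subunit, at 0.73 ± 0.10 and the mitotic kinase Cdk1 at 1.20 ± 0.25. Camera called the list higher with adjusted p = 2.57e-05, and adjusted p = 0.393 with an estimated correlation. In oxidative phosphorylation 21 of 35 genes rose, 23 adjusted over the list alone (median 0.50), including the complex I subunit Ndufs1 with 1.18 ± 0.11. This call (adjusted p = 6.42e-07) had adjusted p = 0.447 with an estimated correlation. In glycolysis and hypoxia 17 of 25 genes rose and 1 fell, 18 and 3 adjusted over the list alone (median 0.95), with the hypoxia-induced Bnip3 at 2.02 ± 0.30 and the glycolytic kinase Pgk1 at 1.28 ± 0.19. That call (adjusted p = 2.23e-06) had adjusted p = 0.282 with an estimated correlation. Cholesterol synthesis had 5 genes of 20 higher and 1 lower, the same adjusted over the list alone, with Fdps at 1.01 ± 0.17 (camera adjusted p = 0.11). The unfolded protein response had 5 of 20 higher and 2 lower, the same adjusted over the list alone, with Asns, an asparagine synthetase, at 1.81 ± 0.21 (camera adjusted p = 0.225). In heat shock and dissociation stress 2 of 15 genes rose, the same adjusted over the list alone (camera adjusted p = 0.491). Melanoma markers had 12 of 15 genes higher, 14 adjusted over the list alone (median 1.79), with camera adjusted p = 4.65e-07, and adjusted p = 0.197 with an estimated correlation.

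Lists of other cells gave smaller or mixed counts. Naive and central T cell genes had 5 of 20 lower and 2 higher, 7 and 2 adjusted over the list alone, with a median of -0.31 that turns to 0.80 with pan-T scaling (camera adjusted p = 0.0683). Myeloid markers had 1 higher and 1 lower of 19, and 1 and 0 adjusted over the list alone (median -0.22, turning to 0.90, camera adjusted p = 0.604), with the lipid carrier Apoe at 1.63 ± 0.40. B cell and plasma cell markers had 2 of 15 lower, the same adjusted over the list alone (median -0.38, turning to 0.72, camera adjusted p = 0.269). CD8 T and NK cell markers had 2 of 11 lower and 1 higher, the same adjusted over the list alone (median -0.94, turning to 0.19, camera adjusted p = 0.11). Stromal and endothelial markers had 3 of 17 higher and 1 lower, the same adjusted over the list alone, with a median of -0.11, which turns to 0.94 with pan-T scaling, and a mean of 0.42 (camera adjusted p = 0.988). Erythroid and platelet markers had none of 6 past the test, also adjusted over the list alone, with a median of 0.21 while camera's direction was lower (adjusted p = 0.998). Among vascular genes the lymphatic receptors Flt4 and Lyve1 had 3.79 ± 0.96 and 3.92 ± 1.16 (edgeR adjusted p = 0.0171 and 0.0359), and Vwf, an endothelial clotting protein, had 1.62 ± 0.41. Without library 2 of the MHCII-deleted tumors Lyve1 was at -0.06 (adjusted p = 0.986) and Flt4 at 2.04 (adjusted p = 0.234). Both calls were also lost with only the groups compared (Lyve1 at 3.84, Flt4 at 3.71) and with the GC index as a covariate (Lyve1 at 0.01, Flt4 at 1.93). That of Lyve1 was lost with DESeq2, limma-voom and no filter too, at values of 3.95, 2.88 and 3.92 (adjusted p = 0.0561, 0.2 and 0.0881). Mecom, a transcription factor, was at 17.1 ± 1.71 CPM (SD, n = 2) against 0.8 ± 0.738 (SD, n = 3), and its call (4.41, adjusted p = 0.0287) was lost without either tumor library of MHCII-deleted mice or without library 1 of the control tumors, and with DESeq2, only the groups compared and the GC index, at values of 4.45, 4.33 and 4.61 (adjusted p = 0.11, 0.0569 and 0.0506). Sfrp2, a secreted Wnt modulator of stromal cells, stood at -4.14 ± 0.92, and Plac8 at -2.56 ± 0.58. The calls of Sfrp2, Vwf and Cxcl10 were lost without library 1 of the MHCII-deleted tumors, at values of -4.03, 1.54 and -1.51. That fit leaves 1 library in the group. Those of Cxcl10 and Lyve1 were also lost without other single libraries. That of Apoe was lost without library 2 of the control tumors (adjusted p = 0.0514). With the GC index as a covariate the calls of Apoe (1.42), Sfrp2 (-3.66) and Plac8 (-1.84) were lost (adjusted p = 0.0567, 0.0835 and 0.0848). That of Sfrp2 was also lost with limma-voom (adjusted p = 0.14) and that of Cxcl10 with no filter (adjusted p = 0.0876). In libraries of 1 level of the GC index, which are fewer, Lyve1 stood at 0.84 and Flt4 at 2.63, and Apoe (1.37), Mecom (4.64) and Cxcl10 (-1.88) also missed the threshold (adjusted p = 0.0834 to 0.72).

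**Figure D2:**
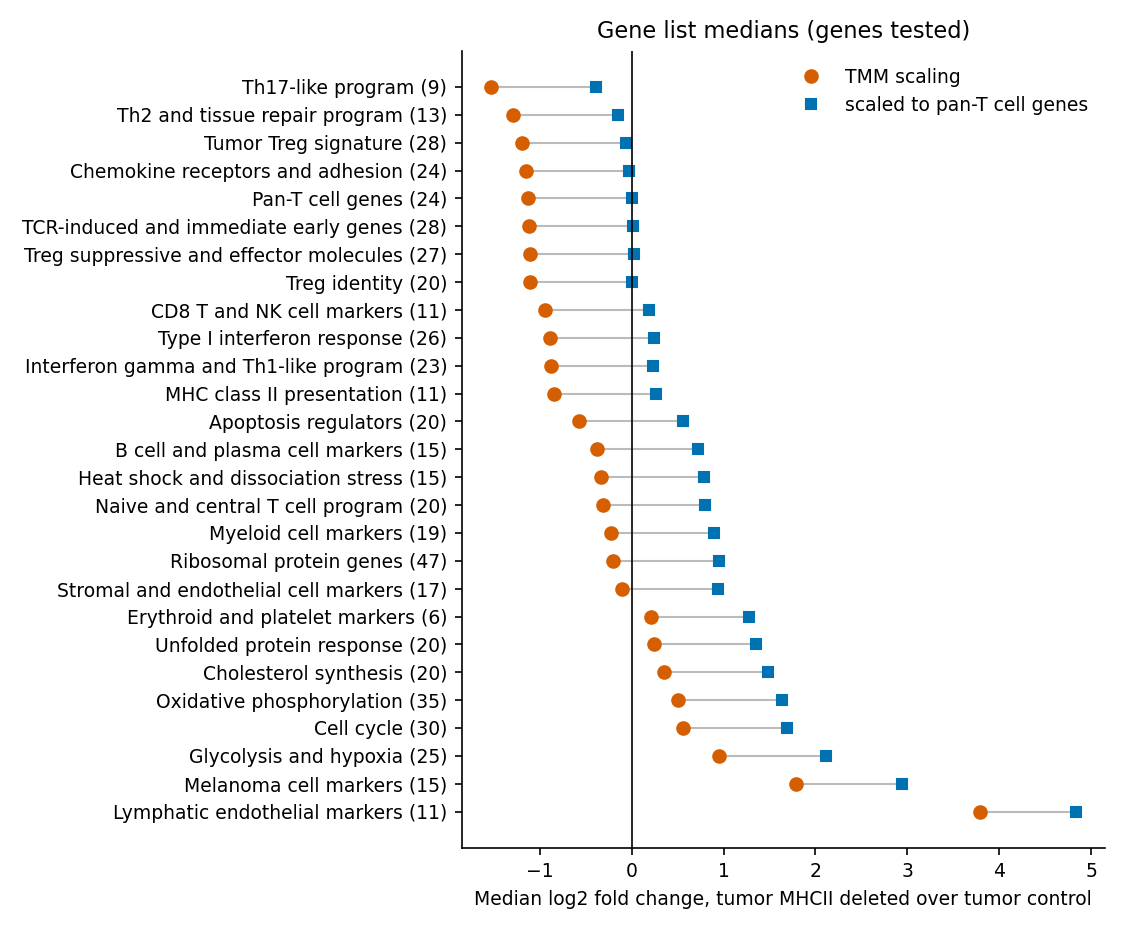
Median log2 fold change of each gene list, tumor of MHCII-deleted over tumor of control mice, with TMM scaling (circles) and scaled to pan-T cell genes (squares), and the number of tested genes in parentheses. The Treg identity list moves from -1.11 to 0.00 and the melanoma list from 1.79 to 2.94.

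Scaling to pan-T cell genes moved the median of all tested genes from 0.10 to 1.24 and the share of called genes that were higher from 52.3% to 99.5% (9390 higher, 43 lower), so the directions given hold only relative to the whole RNA of each library. Of the Treg identity, suppressive and tumor signature lists, 6, 2 and 3 genes were then higher and 0, 3 and 0 lower, and of the naive, apoptosis and ribosomal lists 13, 11 and 42 were higher and none lower. Cell cycle, oxidative phosphorylation and glycolysis then had 30, 34 and 24 genes higher, cholesterol synthesis 19, the unfolded protein response 20 and heat shock 8, with none lower, and the median of heat shock genes turned from -0.33 to 0.79. Of the 40 genes carried through the alternatives, 17 lost their call with this scaling and 2 (Foxp3 and Cd4) turned. Those that lost it were Il2ra, Ctla4, Tnfrsf18, Tnfrsf4, Rgs1, Batf, Cd5, Nfkbia, Irf4, Areg, Gata3, Ccr8, Itgb7, Cd74, Ly6e, Ifng and Cxcl10, with values of -0.70 to -0.05. Il10, Maf and Klrg1 stayed lower with -0.46, -0.39 and -1.15, as did Sfrp2 and Plac8 with -3.05 and -1.43. The 43 lower calls are so few among all calls at the threshold of 0.05 that all of them could be false. Among them was 1 of the 24 pan-T cell genes used for the scaling. With only the 5 tumor libraries in the edgeR fit, 2519 genes were called.

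The deletion effect in LN asks the same of Tregs outside the tumor. Fewer genes passed: of 13920 genes 149 rose and 5 fell. Il10 fell from 8.94 ± 0.653 CPM (SD, n = 3) to 3.06 ± 0.0942 (SD, n = 2), a log2 fold change of -1.55 ± 0.16 (SE; edgeR quasi-likelihood, adjusted p = 0.0255). The other genes that fell were Adam8, a membrane protease, with -1.32 ± 0.24, the chemokine receptor Cxcr6 with -1.19 ± 0.22, the costimulatory receptor Icos with -0.75 ± 0.15 and Ctla4 with -0.64 ± 0.11 (adjusted p = 0.0436 to 0.0497). Foxp3 did not pass (-0.15 ± 0.12, adjusted p = 0.918). Klf2, a factor of T cell quiescence and recirculation (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), rose from 28.0 ± 5.87 CPM (SD, n = 3) to 431 ± 67.8 (SD, n = 2), a log2 fold change of 3.94 ± 0.77 (adjusted p = 0.0497) that turns to -0.27 with a GC index of each library as a covariate. That index separates the LN groups, so the turn cannot tell the deletion from uneven amplification of GC-rich stretches.

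Of 27 suppressive and effector genes 3 fell, and 13 fell when adjusted over the list alone, with a median of -0.46. Camera called this list lower with adjusted p = 4.86e-13, and adjusted p = 0.153 with an estimated correlation. Maf (-0.49 ± 0.15) did not pass over all genes. The tumor Treg signature had 2 of 28 genes lower, 5 adjusted over the list alone (median -0.34, camera adjusted p = 2e-10, and adjusted p = 0.158 with an estimated correlation). In the Th2 and tissue repair list 1 of 13 genes fell, and 5 were lower and 2 higher adjusted over the list alone (median -0.52, camera adjusted p = 0.00086, and adjusted p = 0.416 with an estimated correlation), with the nuclear receptor Rora at -0.58 ± 0.15 (edgeR adjusted p = 0.105). Chemokine receptors and adhesion had 1 of 24 lower, and 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00248, and adjusted p = 0.158 with an estimated correlation). Of 20 Treg identity genes 1 fell, also adjusted over the list alone, with a median of -0.04 that turns to 0.03 with pan-T scaling (camera adjusted p = 0.119). Of 15 melanoma markers 0 passed the edgeR test in LN, also adjusted over the list alone, but camera called the list higher (median 0.94, or 1.05 with the gene undetected in a whole group at its bound, adjusted p = 0.0154, and adjusted p = 0.62 with an estimated correlation). Of the 24 pan-T cell genes 0 passed (median -0.06, or 0.01 with pan-T scaling).

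The genes that rose included the transcription regulators Tle1 (3.20 ± 0.58), Srf (2.96 ± 0.52) and Ctbp1 (2.91 ± 0.56), the RNA-binding protein Zfp36l2 (3.17 ± 0.51) and the ubiquitin ligase adaptor Klhl21 (3.42 ± 0.60). With the GC index as a covariate Tle1 stood at 0.81, Srf at 0.48, Zfp36l2 at 0.32 and Klhl21 at 0.16, and Ctbp1 turned to -0.17, all with the call lost. The index is computed from genes with a stretch above 80% GC and separates the LN groups. A call lost with it therefore cannot tell uneven amplification from the deletion. TCR-induced and immediate early genes had 2 of 28 higher, 6 adjusted over the list alone, with the phosphatase Dusp1 at 1.15 ± 0.22 and the AP-1 subunit Jun at 0.58 ± 0.11 (camera adjusted p = 0.0216, and adjusted p = 0.65 with an estimated correlation). Naive and central T cell genes had 1 of 20 higher, 3 adjusted over the list alone (camera adjusted p = 0.008, and adjusted p = 0.62 with an estimated correlation). Without genes with a GC-rich stretch 0 of the 13 TCR-induced genes left passed (edgeR), with a median of 0.01 against 0.06 before (camera adjusted p = 0.547). Of the 10 naive genes left 0 passed, and the camera call ended (adjusted p = 0.0664) although the median hardly moved, from 0.20 to 0.17. Of the 149 genes that rose, 139 (93.3%) contain a 100-base stretch with more than 75% GC, against 37.8% of the tested genes, and 129 (86.6%) a stretch above 80%, against 19.6%. Both LN libraries of MHCII-deleted mice had a higher index of such genes (0.34 and 0.27) than the LN libraries of control mice (-0.41 to -0.26), and library 2 of the MHCII-deleted tumors had the highest (0.43). Across 7445 genes, which are not independent replicates, the LN effect correlated with the difference between both tumor libraries of MHCII-deleted mice (Pearson r = 0.616, Spearman rho = 0.209).

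**Figure D3:**
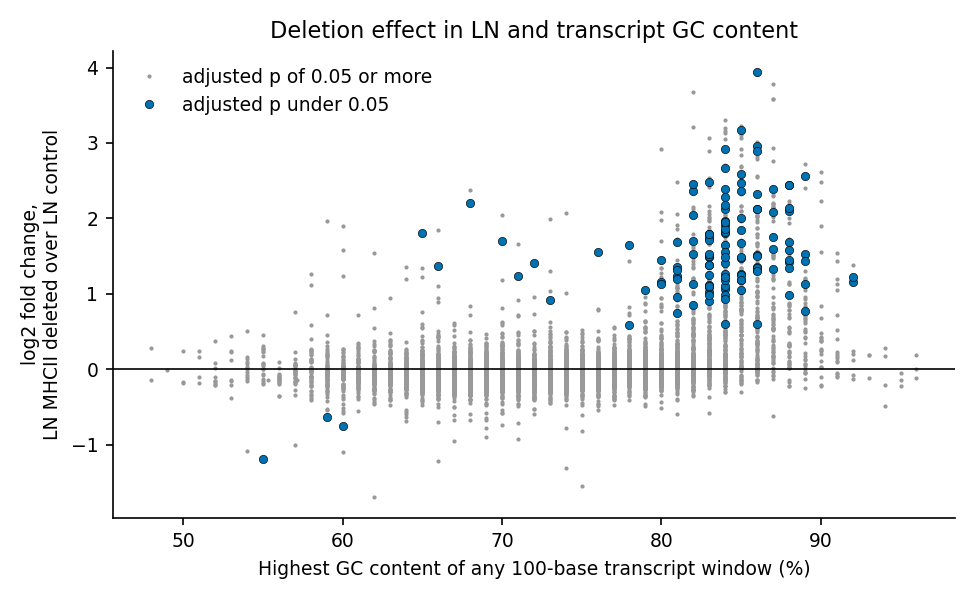
log2 fold change of the deletion effect in LN (vertical) against the highest GC content of any 100-base window of the transcripts of a gene (horizontal, percent), with each point 1 gene and called genes in large symbols. Only the 7445 genes with a mean log2 CPM above 4 in LN are drawn. Of all 149 genes called higher, drawn or not, 139 have a window above 75%, and the 5 called lower have a median of 60%.

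Without the genes that contain such a stretch 3 genes were called, and the count was 0 without any 1 of the 5 LN libraries and with the GC index as a covariate (edgeR; 838 to 1268 at unadjusted p under 0.05). Camera with that covariate called 14 lists, and 5 of the 13 lists called without it stayed called in the same direction, namely suppressive and effector molecules, the tumor Treg signature, cell cycle, cholesterol synthesis and melanoma markers. TCR-induced genes were then called lower, and oxidative phosphorylation and glycolysis higher. As the index separates the LN groups, results with this covariate do not decide between uneven amplification and the deletion. The number of genes was 23 with RLE size factors, 659 with DESeq2, 787 with limma-voom and 806 with only the LN libraries in the fit.

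The tissue comparison in control mice asks which genes set tumor Tregs apart from LN Tregs, the signature that the series title names. Of 13920 genes 3172 rose and 2237 fell in tumor. Areg (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432) rose from 3.44 ± 0.817 CPM (SD, n = 3) to 294 ± 30.8 (SD, n = 3), a log2 fold change of 6.42 ± 0.19 (SE; edgeR quasi-likelihood, adjusted p = 4.73e-08). Ctla4 rose with 2.63 ± 0.10 (adjusted p = 1.83e-07), Il10 with 3.13 ± 0.14 and Fgl2, a secreted suppressor of T cell proliferation, with 3.82 ± 0.16. Foxp3 did not pass (0.10 ± 0.10, adjusted p = 0.456), although it did when scaled to pan-T cell genes (0.37, adjusted p = 0.0413). Melanoma and collagen transcripts came with the tumor libraries: Tyrp1, Pmel and Mlana had 9.79 ± 0.39, 8.50 ± 0.42 and 9.39 ± 0.42, Col3a1 11.42 ± 1.05, and the collagen gene Col6a3, undetected in LN of control mice, was at least 1680-fold higher.

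Suppressive and effector genes had 21 of 27 members higher and 1 lower, 22 and 1 adjusted over the list alone (median 1.36, camera adjusted p = 4.31e-19, and adjusted p = 0.0671 with an estimated correlation). The tumor Treg signature had 22 of 28 higher and 1 lower, 24 and 1 adjusted over the list alone (median 1.22), with Ccr8 at 2.58 ± 0.14, Cxcr6 at 3.55 ± 0.21, the costimulatory receptor Tnfrsf9 at 2.48 ± 0.15 and Tnfrsf18 at 1.57 ± 0.11. Its camera result was adjusted p = 2.76e-12, and adjusted p = 0.0797 with an estimated correlation. Treg identity had 12 of 20 higher and 3 lower, 14 and 3 adjusted over the list alone (median 0.70), with Il2ra at 0.65 ± 0.14, or 0.48 with the call lost with the GC index as a covariate (adjusted p = 0.0727). Camera gave the list adjusted p = 1.5e-05, and adjusted p = 0.13 with an estimated correlation. TCR-induced and immediate early genes had 22 of 28 higher and 3 lower, the same adjusted over the list alone (median 1.67). The NF-kB feedback inhibitors Tnfaip3 and Nfkbia rose with 4.63 ± 0.14 and 2.23 ± 0.10, the orphan receptor Nr4a1 with 3.02 ± 0.16 and the AP-1 subunit Junb with 2.98 ± 0.15. This camera call (adjusted p = 7.13e-19) had adjusted p = 0.0925 with an estimated correlation. In the same comparison 13 of 15 heat shock and dissociation stress genes rose. Whether receptor signaling or dissociation raised the TCR-induced and immediate early genes was not tested. In the Th2 and tissue repair list 11 of 13 genes rose and 1 fell, 12 and 1 adjusted over the list alone (median 3.13), with Rora at 2.32 ± 0.14 and the lipid enzyme Dgat2 at 3.96 ± 0.29 (camera adjusted p = 1.14e-13, and adjusted p = 0.0671 with an estimated correlation). The interferon gamma and Th1-like list had 16 of 23 higher, also adjusted over the list alone (median 1.01), with the chemokine Ccl5 at 4.76 ± 0.38, the receptor chain Il12rb2 at 4.87 ± 0.41 and Ifngr1 at 2.70 ± 0.13 (camera adjusted p = 9.48e-08, and adjusted p = 0.199 with an estimated correlation). CD8 T and NK cell markers summed to 623.4 to 931 CPM in the same tumor libraries, against 88.37 to 115.8 in LN of control mice. Chemokine receptors and adhesion had 13 of 24 higher and 4 lower, 13 and 5 adjusted over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.0925 with an estimated correlation). The melanoma list had 14 of 15 genes higher in the same libraries, also adjusted over the list alone (camera adjusted p = 2.42e-30, and adjusted p = 0.0671 with an estimated correlation).

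Naive and central T cell genes had 14 of 20 members lower and 3 higher, the same adjusted over the list alone (median -2.06, camera adjusted p = 6.52e-13, and adjusted p = 0.0689 with an estimated correlation). Lef1, a factor of naive T cells, stood at -1.64 ± 0.09, the interleukin 6 receptor Il6ra at -2.40 ± 0.16, Treml2 at -3.35 ± 0.24, the quiescence factor Foxp1 at -1.51 ± 0.11 and Dapl1 at -4.76 ± 0.64. Cell cycle genes had 23 of 30 lower, 25 adjusted over the list alone (median -0.68, or -0.41 with 12 lower under pan-T scaling), with the mitotic kinesin Kif20a at -1.78 ± 0.19 and cyclin A, Ccna2, at -1.04 ± 0.13. This call (camera adjusted p = 2.69e-09) had adjusted p = 0.199 with an estimated correlation. Outside the lists, Id3, an inhibitor of E proteins, and the coactivator Pou2af1 stood at -3.81 ± 0.23 and -4.78 ± 0.28. Of 47 ribosomal protein genes 14 fell, 10 adjusted over the list alone (median -0.34, or -0.08 with pan-T scaling), with Rpl4 at -0.63 ± 0.09 (camera adjusted p = 0.00145, and adjusted p = 0.587 with an estimated correlation).

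Glycolysis and hypoxia genes had 21 of 25 members higher, and 21 higher and 1 lower adjusted over the list alone (median 1.25). Melanoma markers summed to 5260 CPM in the same tumor libraries, against 14.3 in LN. The glucose transporter Slc2a1 rose with 1.84 ± 0.10, the lactate exporter Slc16a3 with 2.58 ± 0.12 and the angiogenic factor Vegfa with 8.10 ± 0.46 (camera adjusted p = 1.23e-14, and adjusted p = 0.0941 with an estimated correlation). Cholesterol synthesis had 17 of 20 higher, 18 adjusted over the list alone (median 1.03), with the sterol sensor Insig1 at 2.48 ± 0.24 and the demethylase Cyp51 at 1.53 ± 0.17 (camera adjusted p = 1.48e-05, and adjusted p = 0.288 with an estimated correlation). In heat shock and dissociation stress 13 of 15 genes rose, also adjusted over the list alone (median 1.01), with the stress factor Atf3 at 8.25 ± 0.53 and the chaperone Hspa1a at 8.33 ± 0.74 (camera adjusted p = 6.99e-06, and adjusted p = 0.199 with an estimated correlation). The unfolded protein response had 8 of 20 higher, 10 adjusted over the list alone, with Asns at 3.49 ± 0.21 and Atf4, a regulator of amino acid stress genes, at 1.35 ± 0.10 (camera adjusted p = 0.0305, and adjusted p = 0.372 with an estimated correlation). Among apoptosis regulators 9 of 20 rose and 3 fell, 9 and 4 adjusted over the list alone (camera adjusted p = 0.163). The proapoptotic Pmaip1 and the protective Bcl2l1 had 3.40 ± 0.22 and 1.36 ± 0.10, and the protective Bcl2 had -2.31 ± 0.17. Oxidative phosphorylation had 14 of 35 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.122).

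Markers of other cells were mixed. CD8 T and NK cell markers had 6 of 11 genes higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0845), with Nkg7, a cytotoxic granule gene, at 3.74 ± 0.22. MHC class II presentation had 5 of 11 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.829), with H2-Ab1 at 2.72 ± 0.46, Cd74 at 0.89 ± 0.20 and H2-Ob at -1.70 ± 0.17. With the GC index as a covariate Cd74 was at 0.40 with the call lost (adjusted p = 0.0905). B cell and plasma cell markers had 4 of 15 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.193), with the immunoglobulin heavy chain gene Ighm at -1.34 ± 0.13. Type I interferon genes had 4 of 26 higher and 1 lower, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.314), with Isg20 at 1.41 ± 0.26. Stromal and endothelial markers had 12 of 17 higher and 1 lower, 15 and 1 adjusted over the list alone (camera adjusted p = 0.000111, and adjusted p = 0.144 with an estimated correlation). Scaling to pan-T cell genes moved the share of called genes that were higher from 58.6% to 82.8% (4249 higher, 885 lower) and the median of all genes from 0.08 to 0.35.

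**Figure D4:**
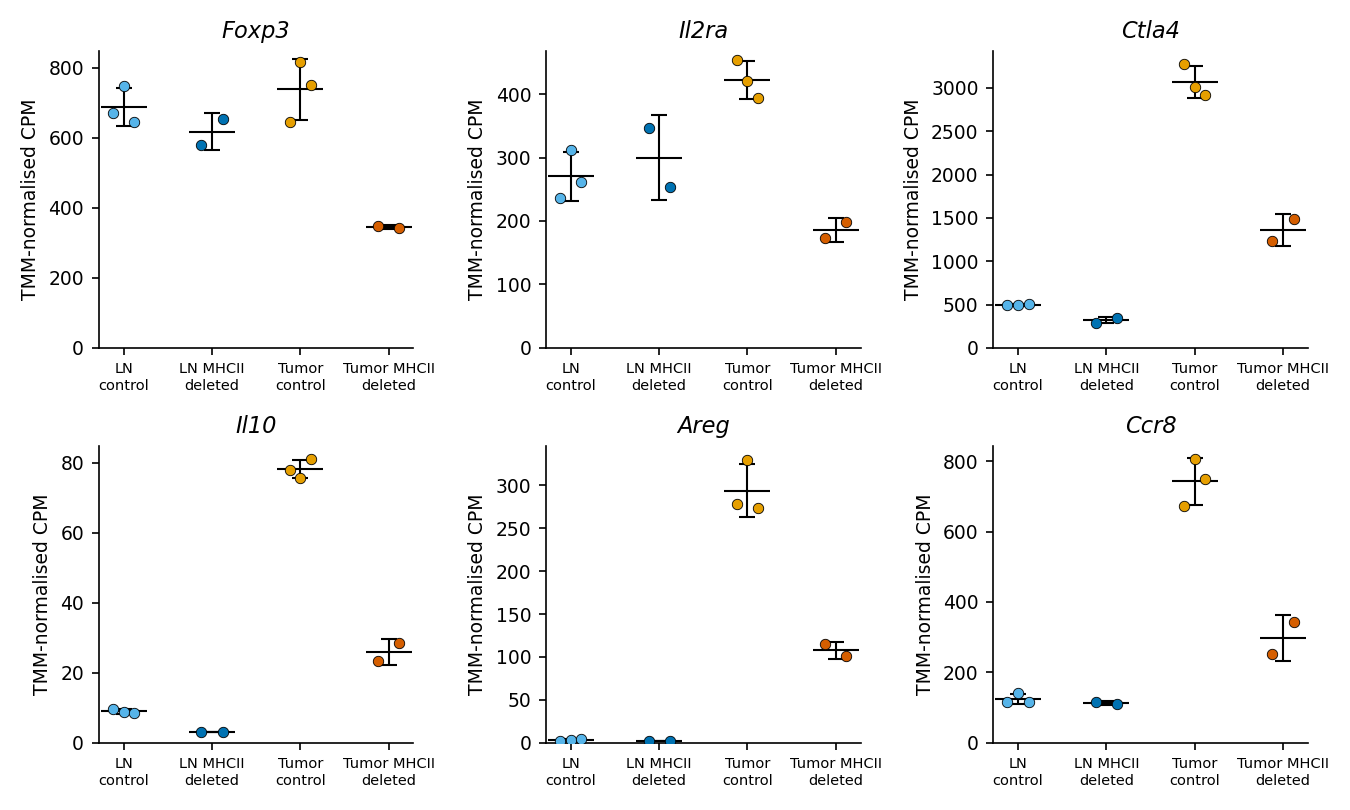
TMM-normalised CPM of single Treg genes in each library by group, with points for libraries, bars for the group mean and SD, and axes that start at 0. Ctla4 has means of 495 and 3070 CPM in LN and tumor of control mice, and Foxp3 has 687 and 738.

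The tissue comparison in MHCII-deleted mice puts the same question to the other genotype. Of 13920 genes 3383 rose and 2792 fell in tumor. Areg rose with 5.63 ± 0.23 (SE; edgeR quasi-likelihood, adjusted p = 7.94e-07), Ctla4 with 2.09 ± 0.12 (adjusted p = 2.05e-06), Il10 with 3.09 ± 0.18 and Fgl2 with 2.90 ± 0.19. Foxp3 fell with -0.84 ± 0.13, Il2ra with -0.69 ± 0.17 and Cd4 with -0.79 ± 0.09, but scaled to pan-T cell genes these turn to 0.50, 0.64 and 0.55. All 24 pan-T cell genes fell (median -1.33, or 0.00 with pan-T scaling), and all 15 melanoma markers rose (median 10.5), also adjusted over the list alone, with Tyrp1 at 10.50 ± 0.48 and Pmel at 9.84 ± 0.54 (camera adjusted p = 8.17e-24, and adjusted p = 0.0957 with an estimated correlation). Sox10, a neural crest factor, was undetected in LN of MHCII-deleted mice and at least 6560-fold higher in tumor.

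Suppressive and effector genes had 15 of 27 higher and 5 lower, 15 and 6 adjusted over the list alone (median 0.62, or 1.97 with 24 higher and 0 lower under pan-T scaling, camera adjusted p = 0.000191, and adjusted p = 0.338 with an estimated correlation). The tumor Treg signature had 14 of 28 higher and 7 lower, the same adjusted over the list alone (median 0.53, or 1.86 with 26 higher and 0 lower under pan-T scaling, camera adjusted p = 0.17), with Cxcr6 at 3.32 ± 0.25, Ccr8 at 1.4 ± 0.17 and Tnfrsf9 at 1.44 ± 0.17. Treg identity had 10 of 20 lower and 7 higher, the same adjusted over the list alone, with a median of -0.26 that turns to 1.07 with pan-T scaling (camera adjusted p = 0.334). Members that fell included the receptors Gpr83 (-4.37 ± 0.37), Izumo1r (-2.48 ± 0.17) and Nrp1 (-1.47 ± 0.12), the last at -0.15 with the call lost under pan-T scaling (adjusted p = 0.26). Naive and central T cell genes had 17 of 20 lower and 1 higher, the same adjusted over the list alone (median -2.14, or -0.80 with 12 lower and 3 higher under pan-T scaling, camera adjusted p = 1.37e-13, and adjusted p = 0.0957 with an estimated correlation). Lef1 stood at -2.41 ± 0.11, Il6ra at -3.53 ± 0.20 and Dapl1 at -5.60 ± 0.82. In the same libraries, in which melanoma markers summed to 16900 CPM in tumor against 23.6 in LN, oxidative phosphorylation had 28 of 35 higher, also adjusted over the list alone (median 0.83), with Ndufs1 at 1.44 ± 0.13 and Sdhd at 1.29 ± 0.11 (camera adjusted p = 1.73e-07, and adjusted p = 0.656 with an estimated correlation). Glycolysis and hypoxia had 21 of 25 higher, and 21 higher and 1 lower adjusted over the list alone (median 2.29), with Slc2a1 at 2.29 ± 0.12, Vegfa at 10.22 ± 0.59 and the glycolytic aldolase Aldoa at 2.82 ± 0.17 (camera adjusted p = 2.58e-20, and adjusted p = 0.138 with an estimated correlation). Cholesterol synthesis had 17 of 20 higher, 18 adjusted over the list alone, with Fdps at 2.24 ± 0.20 (camera adjusted p = 6.24e-07, and adjusted p = 0.394 with an estimated correlation). Tnfaip3, Atf3 and Asns rose with 3.39 ± 0.16, 8.0 ± 0.65 and 5.24 ± 0.28. H2-Ob fell with -2.53 ± 0.22, and Ly6e had -0.95 ± 0.09, which turns to 0.39 with pan-T scaling.

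The Il2ra call was lost without LN library 1 (-0.45, adjusted p = 0.0882) or tumor library 1 (-0.60, adjusted p = 0.0535) of MHCII-deleted mice. Scaling to pan-T cell genes moved the share of called genes that were higher from 54.8% to 97.4% (9474 higher, 253 lower) and the median of all genes from 0.07 to 1.4.

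The tissue effects of both genotypes overlapped. Of the genes past the threshold, 2252 rose in tumor in both genotypes, where 770.9 would be expected by chance, and 1388 fell in both, where 448.7 would be expected. Another 113 genes passed in opposite directions. Across the 13920 genes, which are not independent replicates, both log2 fold changes correlated with Pearson r = 0.834 and Spearman rho = 0.725. Tumor libraries of both genotypes also held RNA of other cells, with melanoma marker sums of 5260 and 16900 CPM against 14.3 and 23.6 in LN. The expected counts and correlations do not take this into account, so the overlap cannot be read as one of Treg genes alone. For the deletion effect, 51 genes rose in both tumor and LN (22.4 expected), 5 fell in both (0.7 expected) and 3 passed in opposite directions, with r = 0.119 and rho = 0.146 across the same genes. Of the 149 genes called higher in LN, 139 have a GC-rich window. In the MHCII-deleted tumors, 130 of the 149 were higher in library 2, which had the highest GC index, than in library 1. The expected counts leave this out, so the 51 cannot be read as a shared effect of the deletion. The 5 that fell in both were the 5 called lower in LN. Of these, scaled to pan-T cell genes, Il10 stayed lower in tumor (-0.46, adjusted p = 0.0211), and the calls in tumor of Ctla4 (-0.05), Icos (-0.06), Cxcr6 (-0.31) and Adam8 (-0.44) were lost (adjusted p = 0.0847 to 0.696).

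The difference of the deletion effect between tumor and LN was tested as an interaction, which is equally the difference of the tissue effect between the genotypes. Of 13920 genes 915 were lower in this difference and 576 higher. Treg genes were lower: Foxp3 had a log2 difference of -0.94 ± 0.16 (SE; edgeR quasi-likelihood, adjusted p = 0.00905), Cd4 -1.0 ± 0.12 and Batf -1.02 ± 0.16, but scaled to pan-T cell genes these turn to 0.13, 0.07 and 0.05. Il2ra had -1.34 ± 0.22 (adjusted p = 0.00812), or -0.28 with the call lost under pan-T scaling (adjusted p = 0.337). Ctla4 had -0.54 ± 0.15 (adjusted p = 0.0467), which turns to 0.52 with pan-T scaling and is then called in the other direction (adjusted p = 0.0145). The median difference of the 24 pan-T cell genes was -1.10 in the same libraries.

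Treg identity had 16 of 20 genes lower, and 16 lower and 1 higher adjusted over the list alone, with a median of -0.98 that turns to 0.08 with pan-T scaling (camera adjusted p = 1.32e-13, and adjusted p = 0.0561 with an estimated correlation). TCR-induced and immediate early genes had 18 of 28 lower, 23 adjusted over the list alone (median -1.17, or -0.13 with pan-T scaling), with Nfkbia at -1.36 ± 0.15, Irf4 at -1.31 ± 0.20 and Junb at -1.52 ± 0.23 (camera adjusted p = 4.95e-17, and adjusted p = 0.121 with an estimated correlation). Other lower genes were Rgs1 (-1.71 ± 0.21), Gata3 (-1.23 ± 0.23), Ccr8 (-1.18 ± 0.21), the selectin ligand Selplg (-1.10 ± 0.13), Itgb7 (-1.09 ± 0.13), Ly6e (-1.17 ± 0.11) and the lysosomal protease Ctss (-1.16 ± 0.21). With pan-T scaling the calls of Gata3, Ccr8, Selplg, Itgb7, Ly6e and Ctss were lost, with values of -0.16, -0.13, -0.04, -0.03, -0.11 and -0.11, and so were those of Nfkbia, Irf4 and Junb (-0.30, -0.24 and -0.47). Cell cycle genes had 10 of 30 higher, 19 adjusted over the list alone (median 0.75), with Rrm2, a nucleotide reductase subunit, at 1.26 ± 0.22 and Mcm2 at 0.76 ± 0.15 (camera adjusted p = 4.15e-10, and adjusted p = 0.249 with an estimated correlation). Oxidative phosphorylation had 13 of 35 higher, 21 adjusted over the list alone (median 0.63), with Ndufs1 at 1.32 ± 0.16 and Sdhd at 0.94 ± 0.14 (camera adjusted p = 4.39e-11, and adjusted p = 0.303 with an estimated correlation). Glycolysis and hypoxia had 13 of 25 higher, and 17 higher and 1 lower adjusted over the list alone (median 0.94), with Pgk1 at 1.58 ± 0.27 and Bnip3 at 2.58 ± 0.46 (camera adjusted p = 6.14e-10, and adjusted p = 0.212 with an estimated correlation). Asns had 1.75 ± 0.31. Zfp36l2, the kinase gene Pim1 and Socs1, a suppressor of cytokine signaling, had -2.95 ± 0.73, -2.26 ± 0.50 and -2.21 ± 0.51, and the calls of Pim1 and Socs1 were lost with pan-T scaling (-1.23 and -1.16).

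Leaving out library 2 of the LN of MHCII-deleted mice ended the calls of Ctla4, Mcm2, Bnip3, Zfp36l2, Pim1 and Socs1 (adjusted p = 0.0542 to 0.192), and Ctla4, Zfp36l2, Pim1 and Socs1 were each also lost without other single libraries. RLE size factors (-0.47, adjusted p = 0.0724) and leaving out GC-rich genes (-0.56, adjusted p = 0.0521) also ended the call of Ctla4, and no filter that of Zfp36l2 (-2.95, adjusted p = 0.087). With the GC index as a covariate 10 of the 25 genes carried through the alternatives lost their call, namely Il2ra (-1.12), Ctla4 (-0.37), Ccr8 (-0.97), Ctss (-0.84), Rrm2 (1.18), Mcm2 (0.79), Pgk1 (1.10), Asns (1.66), Pim1 (-1.40) and Socs1 (-1.38), with adjusted p = 0.0578 to 0.264. The share of called genes that were higher moved from 38.6% to 99.7% with pan-T scaling (6031 higher, 21 lower), with the median of all genes at -0.01 and 1.06.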

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

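The results of this part were singled out because the deletion effect differed between tumor and LN in the interaction test, and the tests of their explanations, pan-T scaling and the settings by GC were chosen only after the results were seen, but the count of other splits of the samples before. In total 1491 genes differed.

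Among the gene lists that camera called at its preset correlation, the median differences were -0.98 for Treg identity, -0.78 for suppressive and effector molecules, -0.83 for the tumor Treg signature, -0.69 for naive and central T cell genes, -1.17 for TCR-induced genes, -0.79 for chemokine receptors and -0.57 for apoptosis regulators. They were -1.27 for type I interferon, -0.87 for interferon gamma, -0.97 for Th2, -0.75 for Th17-like, -0.67 for heat shock and -1.16 for MHC class II genes. The lists with higher values were cell cycle with 0.75, oxidative phosphorylation with 0.63, glycolysis with 0.94, cholesterol synthesis with 0.44 and melanoma markers with 0.91. None of these calls held with an estimated correlation. Scaled to pan-T cell genes, the medians turned to 0.08 for Treg identity, 0.29 for suppressive molecules, 0.24 for the tumor Treg signature, 0.39 for naive genes, 0.30 for chemokine receptors and 0.51 for apoptosis regulators, and to 0.20 for interferon gamma, 0.12 for Th2, 0.30 for Th17-like and 0.39 for heat shock genes. Those of TCR-induced, type I interferon and MHC class II genes were -0.13, -0.22 and -0.11, and the 5 higher lists had 1.82, 1.72, 2.03, 1.49 and 1.98 in the order given. Without genes with a GC-rich window, which leaves fewer members, the camera calls of Th2, Th17-like and melanoma genes ended (adjusted p = 0.0524, 0.127 and 0.0634) at medians of -1.03, -0.90 and 0.79.

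Among the printed genes that differed, Sfrp2 had a log2 difference of -4.71, Zfp36l2 -2.95, Pim1 -2.26, Socs1 -2.21 and Dusp1 -1.73. Zfp36l2 and Dusp1 were also called higher in LN, where the GC index separates the groups. That part of their difference cannot be told apart from uneven amplification of GC-rich stretches. With the GC index as a covariate the calls of Pim1 (-1.40) and Socs1 (-1.38) were lost (edgeR adjusted p = 0.115 and 0.174), and that of Zfp36l2 was kept. Values between -1.71 and -1.30 were found for Rgs1 (-1.71), Ifng (-1.58), Junb (-1.52), Nfkbia (-1.36), Il2ra (-1.34) and Irf4 (-1.31). Somewhat smaller differences were those of Tnfaip3 (-1.24), Gata3 (-1.23), Pmaip1 (-1.19), Ccr8 (-1.18), Ly6e and Nr4a1 (both -1.17), Ctss (-1.16), Cd5 (-1.15), Nkg7 and Izumo1r (both -1.14), Il6ra (-1.13) and Selplg (-1.10). Itgb7 had -1.09, Tnfrsf9 -1.04, Maf -1.03, Batf -1.02, and Tnfrsf18 and Cd4 both -1.0. Nrp1 had -0.96, Foxp3 -0.94, Fgl2 -0.92, Tnfrsf4 -0.87, Lef1 -0.76, Ifngr1 -0.74, Bcl2l1 -0.59 and Ctla4 -0.54. Higher differences were those of Mcm2 (0.76), Sdhd (0.94), Fdps (1.03), Aldoa (1.17), Kif20a (1.23), Rrm2 (1.26), Cdk1 (1.29), Ndufs1 (1.32), Pgk1 (1.58), Asns (1.75) and Bnip3 (2.58). Of the 25 differences carried through every alternative, 10 lost their call with the GC index as a covariate, and with pan-T scaling 12 lost it and 4 turned.

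In tumor of MHCII-deleted mice, T cell and Treg genes were lower and melanoma genes higher. All 24 pan-T cell genes were lower, with a median of -1.13 (SD 0.21), and the 15 melanoma markers had a median of 1.79 (SD 0.23), with 12 of them past the test, so more melanoma RNA in these libraries is a candidate explanation, although the sort by reporter would be meant to remove such cells. The tables argue against a lower Treg program within the T cells as the whole cause, since the 59 genes of the Treg lists outside the pan-T list moved from a median of -1.12 to 0.01 (SD 0.66, 30 higher and 29 lower) with pan-T scaling, far from the -1.12 to be explained. They also argue against uneven amplification of GC-rich stretches, since the 23 pan-T cell genes without such a stretch had a median of -1.10 (SD 0.16). A change of other cells in the tumor that follows from the deletion was not tested and stays open.

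In LN of MHCII-deleted mice, 149 genes were called higher. Of them 93.3% have a GC-rich window, against 30.9% to 46.3% in random lists of other genes of like level, which uneven amplification of GC-rich stretches would need. It cannot be told apart from the deletion itself for these genes, because the GC index separates the LN groups (lowest 0.27 with the deletion, highest -0.26 in controls). Without genes with a GC-rich window 3 genes were called, namely Il10 at -1.50 (adjusted p = 0.0242), Prickle1 at 2.14 and Nrip1 at 1.41 (both adjusted p = 0.0319). Prickle1 and Nrip1 were chosen for naming after their values were seen.

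For the tissue effect in control mice, the real split of the 6 libraries gave 5409 genes and the highest of the other splits gave 0 (edgeR). The 10 possible splits are too few for a share under 0.05.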

How the results depend on the processing

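The settings without GC-rich genes, with the GC index and with pan-T scaling were tests chosen only after the results were seen. Over the alternatives fixed beforehand, 2881 of 3071 values of the 166 results for single genes carried through them kept direction and side of the threshold, 184 lost the call, 5 gained it and 1 reversed, and 136 of the 166 held in all of them. These pooled figures hide that the LN deletion effect held least. With RLE size factors 12 of its 17 genes lost the call, against 1 of 25 in the interaction and 0 in the other comparisons. With the replicate block 13 of the 17 lost it. Where counts moved, the cause was not tested unless the setting itself removes genes or samples.

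With fewer samples in the fit (only the groups compared) the deletion effect called 2519 genes in tumor and 806 in LN. The LN count was 23 with RLE size factors, 659 with DESeq2 and 787 with limma-voom, and DESeq2 called 2487 for the interaction. The replicate block, in which libraries share only a number (correlations of 0.02 to 0.05 over 5 pairs), gave 0 genes in LN (edgeR, 1140 at unadjusted p under 0.05), 3144 in tumor, 4903 and 5737 for the tissue effects in control and MHCII-deleted mice (4875 and 5736 within genotype) and 1126 (1177) for the interaction.

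Leaving out 1 library gave 2745 to 3695 genes for the tumor deletion effect, 4157 to 5671 and 4293 to 6326 for the tissue effects, and 0 to 611 for LN. The LN count was 0 without any 1 of the 5 LN libraries (edgeR, 960 to 1268 at unadjusted p under 0.05). It was 364, 68 and 20 without control tumor library 1, 2 and 3, and 611 and 592 without MHCII-deleted tumor library 1 and 2. The interaction ranged from 527 to 2281: 884, 973 and 846 without LN control library 1, 2 and 3, 735 and 527 without LN MHCII-deleted library 1 and 2, and 796 and 2281 without MHCII-deleted tumor library 1 and 2. A lone library left in a group is assumed to vary like the others. The Lyve1 and Flt4 calls in tumor were lost with the replicate block (edgeR adjusted p = 0.422 and 0.0941). In the interaction the block ended the calls of Ctla4, Zfp36l2, Pim1 and Socs1 (edgeR adjusted p = 0.0711, 0.0786, 0.0517 and 0.0531). The Lyve1 value in tumor ranged from -0.06, without MHCII-deleted tumor library 2, to 4.87.

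Without genes with a GC-rich window, which tests fewer genes, the counts were 2599 in tumor, 3 in LN (323 at unadjusted p under 0.05), 3387 and 3903 for the tissue effects, and 2284 for their overlap. With the GC index as a covariate they were 0 in LN (edgeR, 838 at unadjusted p under 0.05) and 363 for the interaction, and in LN Klf2 turned to -0.27, Ctbp1 to -0.17 and Foxp3 to 0.02. The index separates the LN groups, so these values do not decide between uneven amplification and the deletion.

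Scaled to pan-T cell genes, the counts were 9433 in tumor, 423 in LN, 9727 for the tissue effect in MHCII-deleted mice and 6052 for the interaction. With GC-rich genes also left out they were 3 in LN, 3049 for the tissue effect in control mice, 4207 for the interaction and 2353 for the overlap. With pan-T scaling, and with both, Foxp3 turned to 0.04 and 0.07 and Cd4 to 0.08 and 0.11 in the tumor deletion effect. In the tissue effect of MHCII-deleted mice Foxp3 turned to 0.50 and 0.51, Il2ra to 0.64 and 0.64, Cd4 to 0.55 and 0.55 and Ly6e to 0.39 and 0.40. In the interaction Foxp3 turned to 0.13 and 0.17, Ctla4 to 0.52 and 0.56, Cd4 to 0.07 and 0.11 and Batf to 0.05 and 0.09. In the interaction, only the values of Ctla4 passed the test (edgeR adjusted p = 0.0145 and 0.0095), and in the tumor deletion effect none did. All of those in the tissue effect of MHCII-deleted mice passed it (edgeR adjusted p = 0.00278 to 0.0153).

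Camera with an estimated correlation called 6 of 16 lists in the tumor deletion effect and 0 in the other comparisons, against 13 in LN, 16 and 12 for the tissue effects and 18 for the interaction at the preset correlation. In LN, adjusted p over all alternatives ranged from 8.07e-12 to 0.734 for Il10 and from 3.42e-06 to 0.734 for Ctla4.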

Other observations

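The tests of explanations and of the hypothesis in this part, and the settings without GC-rich genes and with the GC index, were chosen only after the results were seen, and the gene list tests before. In LN of MHCII-deleted mice some further programs leaned to 1 side without single genes passing over all genes. Heat shock and dissociation stress genes had a median of 0.37 with 0 of 15 genes past the edgeR test, also adjusted over the list alone (camera adjusted p = 0.00389, and adjusted p = 0.62 with an estimated correlation). Cell cycle genes had a median of -0.15 with 0 of 30 past the test (camera adjusted p = 0.000493, and adjusted p = 0.62 with an estimated correlation), and oxidative phosphorylation and glycolysis both had -0.13 (camera adjusted p = 0.00389 for each, and adjusted p = 0.68 and 0.62 with an estimated correlation). Without genes with a GC-rich window, these 2 calls were lost, with medians of -0.09 and -0.08 (camera adjusted p = 0.0664 and 0.0799), and with the GC index as a covariate camera called both lists higher and no longer called heat shock genes. Erythroid markers summed to 70.65 CPM in LN library 2 of MHCII-deleted mice, and to between 0.1136 and 1.052 CPM in the other LN libraries.

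Suppressive and effector genes had a median of -0.46 in LN of MHCII-deleted mice, with 3 of 27 past the test. Uneven amplification of GC-rich stretches is argued against, since the 22 members without such a stretch had a median of -0.42, below that of random lists (-0.12 to 0.02), in the lowest 0.01%, the smallest share that 10000 lists can give. These lists treat genes as independent, so the share does not measure the spread between libraries. Dilution by RNA of cells that are not T cells is argued against too, since pan-T cell genes had a median of -0.06 (SD 0.11). These genes are shared by T cells in general, so a larger share of other T cells was not tested and stays open. A lower effector program that follows from the deletion may account for it, but the list had adjusted p = 0.153 with an estimated correlation (camera), so with 2 and 3 libraries this stays open.

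A further hypothesis was that genes still lower in tumor of MHCII-deleted mice after pan-T scaling are also lower in LN. There were 43 such genes, so few among all calls with this scaling that all of them could be false. Of them 8 were receptor segments, and 22 had at least 10 CPM. The 20 of those 22 that are not receptor segments were tested. Of these 20, 16 had a negative value in LN, but only Il10 was past the test there (adjusted p = 0.0255, and 0.142 to 1 for the other 15). The median of the 20 was -0.25 against -0.11 to 0.09 in random lists, in the lowest 0.01%, the smallest share that 10000 lists can give. Such lists treat genes as independent, so this share measures the drawing of genes and not the spread between libraries. The 17 genes outside the suppressive and effector list had a median of -0.20 (lowest 0.02%), and the 16 without a GC-rich window -0.27. The values go with the hypothesis, which may reflect an effect of the deletion shared by both tissues. The LN values took no part in choosing the genes, but the hypothesis was framed after the results of both tissues had been seen. With 2 and 3 libraries in LN it stays open.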
